A study of Mus musculus with 32 samples.

How the data were processed

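RNA was sequenced from extraocular muscle (EOM, the muscles that move the eye), tibialis anterior (TA, a limb muscle), oculomotor neuron samples (CN3) and abducens motor neuron samples (CN6). Each of the 4 tissues has 4 libraries from the albino strain B6(CG)Tyr(c-2J)/J and 4 from pigmented C57BL/6, which makes 32 libraries. Per the labels, RNA was extracted with the RNeasy Fibrous Tissue or Lipid Tissue Mini Kit. The labels do not say that the replicates are separate animals, so each p measures the spread between these samples. They give neither the sex of the mice nor the time of collection.

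The deposited table holds raw read counts per gene symbol, with no normalization, for 24421 genes. The submitters' processing notes name Trimmomatic 0.33, FastQC, HISAT2 2.1.0 with the mouse build mm10, featureCounts and edgeR. They name no annotation, strand setting or filter, so reads of genes that overlap on opposite strands may be counted together. Of the gene names, 27 are date-like and hold at most 0.309% of the reads of a library. Library totals ran from 18544334 to 44254021 counts. By group they were 18544334 to 24446789 for C57BL/6 EOM, 23095793 to 27965207 for C57BL/6 TA, 30694749 to 44254021 for C57BL/6 CN3 and 31265634 to 39829893 for C57BL/6 CN6. The albino libraries ran from 18996461 to 34550801 counts. Positions and exon lengths come from GENCODE on the same build and were found for 23350 symbols (95.6%).

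Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr, libraries were scaled with TMM, and a quasi-likelihood F test compared albino with C57BL/6 in each tissue. The same model tested whether the genotype difference differed between EOM and TA or between CN3 and CN6, and compared the tissues themselves. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. CPM values are edgeR's counts relative to the deposited library totals, and log2 CPM values use a prior count of 2. Log2 fold changes are given with the standard error from the F statistic, and group means with the standard deviation (SD). Differences are albino relative to C57BL/6 unless another pair is named.

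Groups, comparisons, gene lists and named genes were chosen before the data were examined. There are 41 gene lists, 29 used for muscle and 27 for CN3 and CN6, some for both. Those with at least 3 tested genes were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment within a tissue. Camera with an estimated correlation and fry were run beside it. Counts of called list members are also given adjusted over the list alone. Named genes are Tyr, the 10 largest changes per direction with a mean CPM of at least 1 and no overlap between groups, and up to 4 members per list with the smallest adjusted p. Symbols that are model numbers were left out. Further, 2 genes that meet these rules are not reported here. Named too are 5 genes per direction for each genotype by tissue test, 10 per direction for each tissue comparison at a mean CPM of at least 5, 12 genes known to differ between C57BL/6 substrains, and the sex-linked genes.

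The first use of the table was a check of each library against its label, with the fast fibre list for muscle and the glutamatergic list for brain. A library was called muscle where the mean log2 CPM of the first list was higher. In 8 albino libraries the kind of tissue contradicted the label. No library was moved to another group. The planned comparisons were run with all libraries as labelled. They were then run again on the 24 libraries whose markers match their label, which leaves 4 C57BL/6 and 2 albino libraries per tissue. That second set was chosen after seeing the data, as was a fit of the genotype over the 4 tissues together. Its named genes follow the same rule over the libraries kept.

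Alternatives tried were DESeq2 size factors and upper quartile factors in edgeR, no filter, a filter of CPM at least 1 in at least 4 libraries, the DESeq2 1.42.0 Wald test, and limma voom with sample quality weights. Others were all tissues in 1 fit, the level of the Y-linked genes as a covariate, a replicate block, and leaving out each library in turn. After seeing the data, offsets for GC content and exon length were added, as natural splines with 5 degrees of freedom each. Up to 100 other splits of the libraries (seed 1) were tested in place of the real one.

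The fits were tested on simulated data of the size of the matching set, with genes changed 1.5-, 2- and 4-fold, of which those that passed the filter were counted. Of 67, 67, 65 and 66 genes changed 2-fold, 62.7% were recovered in EOM, 71.6% in TA, 72.3% in CN3 and 75.8% in CN6, with 11, 8, 6 and 14 false calls. A list shifted 1.5-fold was called in each of the 4 tissues and 0 other lists were. Simulated genes were drawn independently of each other, so this does not measure false list calls in the real libraries. Other splits of the matching libraries called a median of 8 lists in EOM, 6 in TA, 7 in CN3 and 8.5 in CN6. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes encoded in mitochondrial DNA are absent from the tested genes, so the list of mitochondrially encoded genes has 0 tested members.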

Results

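The albino strain B6(CG)Tyr(c-2J)/J carries a changed Tyr, the gene of tyrosinase, the first enzyme of melanin synthesis, and the series asks how its nystagmus, an involuntary oscillation of the eyes, relates to gene expression. Eye muscles, a limb muscle and the oculomotor and abducens neuron samples of albino and pigmented mice were compared. Tyr itself (chromosome 7, 87424771 to 87493512, mm10) stayed at or below 0.64 CPM in every library. It could be tested in EOM only, where its log2 fold change of −0.83 ± 0.73 (0.260 against 0.472 CPM) was not called (adjusted p = 0.43).

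The first result concerns the labels. Muscle and brain express sharply different genes, and 8 of the 16 albino libraries carried the genes of the other kind of tissue. The libraries labelled albino EOM 1 and 2 and albino TA 1 and 2 looked like brain, and those labelled albino CN3 3 and 4 and albino CN6 3 and 4 looked like muscle. All 16 C57BL/6 libraries were muscle or brain as labelled. Ckm, the muscle creatine kinase, reached 4279 to 4826 CPM in C57BL/6 EOM and 12834 to 13305 CPM in C57BL/6 TA. The libraries labelled albino EOM 1 and 2 held at most 0.218 CPM of it, while those labelled albino CN6 3 and 4 held 13007 and 13325 CPM. Snap25, a protein of synaptic vesicle release, read 2447 and 2509 CPM in the libraries labelled albino EOM 1 and 2, against 5.87 to 34.2 CPM in C57BL/6 EOM. The mean log2 CPM of the fast fibre list was 0.11 and 0.46 in those libraries and 11.08 to 11.23 in C57BL/6 EOM.

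**Figure D1:**
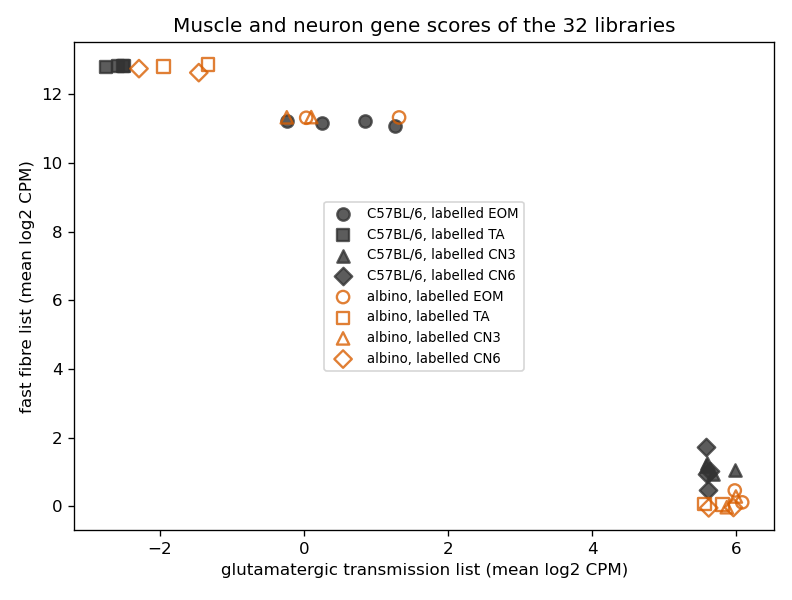
Mean log2 CPM of the fast fibre list (vertical axis) against that of the glutamatergic list (horizontal axis), with 1 point for each of the 32 libraries, by genotype and labelled tissue. The 8 albino libraries whose markers contradict their label lie among libraries of the other kind of tissue.

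Compared as labelled, the albino groups mix muscle with brain, and few genes stood out from that spread. In EOM 1 of 15227 genes was called. It was Dbp, a clock-controlled transcription factor, at a log2 fold change of −2.29 ± 0.13 (adjusted p = 0.00394, 15.8 ± 1.20 against 71.7 ± 6.82 CPM, SD, n = 4 and 4). In TA 18 of 13193 genes were called, 12 higher and 6 lower. The mitochondrial transhydrogenase Nnt fell by 2.75 on the log2 scale (adjusted p = 0.0071), while Dkk3, a secreted protein of the Wnt pathway, rose by 2.58 and the macrophage genes Tyrobp and C1qb by 2.29 and 1.88. No gene was called by edgeR in CN3 or CN6 (0 and 0), although 2966 and 2659 genes had an unadjusted p under 0.05. DESeq2 called 1235 and 777 there and limma voom 16 and 2. In EOM 4360 genes had an unadjusted p under 0.05, DESeq2 called 3796 genes and limma voom 12754. The count in EOM was 0 without C57BL/6 EOM 1 or 4 and 2206 without albino EOM 4. In TA it was 0 without any single C57BL/6 TA library or albino TA 1, 1 without albino TA 2, 2515 without albino TA 3 and 2578 without albino TA 4. In CN6 it was 1 without albino CN6 2.

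The genotype difference as labelled differed between EOM and TA for 33 of 16443 genes, 2 higher and 31 lower in EOM. That count was 0 to 10 without any single C57BL/6 EOM or TA library, 1 without albino TA 1 or albino TA 2, 2 without albino EOM 2, 13 without albino EOM 1, 160 without albino TA 3 and 144 without albino TA 4. Between CN3 and CN6 it differed for 0 of 16552 genes by edgeR, with 700 at an unadjusted p under 0.05, 12 by DESeq2 and 0 by limma voom. Camera called 19 lists in EOM, all lower, 7 in TA, 15 in CN3 and 13 in CN6, and 0 in each tissue with an estimated correlation. The list count was 10 and 9 in EOM without albino EOM 1 and 2, 2 in TA without albino TA 1 or 2, and 11 without albino TA 3 or 4. EOM and TA differed in 4345 genes and CN3 and CN6 in 28. The second count was 18 without C57BL/6 CN6 2, C57BL/6 CN3 4 or albino CN3 4, 16 without C57BL/6 CN6 3 and 76 without albino CN6 1. Results that follow come from the 24 libraries whose markers match their label, with 4 C57BL/6 and 2 albino libraries in each tissue (n = 4 and 2), a set chosen after seeing the data. The check separates muscle from brain. Myh13 also sets the kept EOM and TA libraries apart as labelled, with 4378 and 4459 against 23.8 and 24.9 CPM in albino and 4272 to 4980 against 23.8 to 34.8 CPM in C57BL/6. Neither measure separates CN3 from CN6. They thus leave unchecked whether the kept albino libraries of CN3 and CN6 are rightly told apart, on which the genotype results there depend. Hoxb3 and Tph2, given below, set albino CN6 1 far from C57BL/6 CN6 and leave its site in doubt.

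In EOM more genes of mitochondrial respiration, fat burning and ribosomes were called higher than lower in the matching albino libraries, and more genes of connective tissue lower than higher. None of these lists was called with an estimated correlation (adjusted p = 0.807 for each). Their clock genes were shifted, with the activator high and its targets low. Of 15397 genes, 4934 were called, 2229 higher and 2705 lower, and 576 of them changed at least 2-fold (180 higher and 396 lower). Upper quartile factors turned the balance of higher and lower genes to 2881 and 2390, and all tissues in 1 fit to 3174 and 2773. With the replicate block 2641 genes were called.

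Most clock genes changed in EOM, with 4 higher and 12 lower of 19 tested genes (5 and 12 adjusted over the list alone, camera adjusted p = 0.00296, adjusted p = 0.807 with an estimated correlation). Arntl, which encodes the clock activator BMAL1, rose by 3.35 ± 0.19 on the log2 scale, from 5.03 ± 1.34 to 50.4 ± 3.24 CPM (adjusted p = 1.3e-04). Per2, a repressor of that activator, fell by 3.44 (adjusted p = 1.3e-04), and Ciart, another repressor, by 3.60 (adjusted p = 1.1e-04). The clock output genes Dbp and Hlf fell by 2.26 and 2.41. For each of these 5 genes both albino libraries lay outside the range of the 4 C57BL/6 libraries. Named genes were chosen for no overlap between groups or for a small adjusted p, so this is no separate evidence.

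Several energy lists of EOM were called higher at the preset correlation and none at an estimated one. The oxidative phosphorylation list, the subunits of the respiratory chain, had 35 higher and 0 lower of 44 genes (40 adjusted over the list alone, camera adjusted p = 7.0e-15). Ndufa2 and Ndufa5 of complex I rose by 0.94 and 0.64 and Cox6c of complex IV by 0.64. The fatty acid oxidation list had 14 higher and 1 lower of 20 (17 and 1 adjusted over the list alone, camera adjusted p = 1.4e-05). Pdk4, which holds back the use of glucose, rose by 1.89 ± 0.28 (148 ± 37.8 to 538 ± 262 CPM, adjusted p = 0.00194), the mitochondrial carrier Ucp3 by 1.86 and the fatty acid enzyme Eci1 by 0.88. Glycolysis had 6 higher and 1 lower of 18, with 11 not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.00698), among them Ldhb at 0.58. The ribosomal protein list had 33 higher and 0 lower of 38 (35 adjusted over the list alone, camera adjusted p = 4.0e-14). With an estimated correlation the adjusted p was 0.887 for glycolysis and 0.807 for the other 3 lists. Measured beside these groups, the genotype difference followed base composition over all tested genes with an annotation. Its median log2 fold change was −0.39 in the lowest of 4 equal groups by GC content and 0.29 in the highest, and 0.28 in the shortest of 4 by length and −0.29 in the longest. With GC and length offsets 1733 genes were called, 8 respiratory and 5 ribosomal genes stayed called, and Ndufa2, Ndufa5 and Ldhb lost their calls.

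Contractile, connective and vascular genes of EOM moved less uniformly. Myh15, a myosin heavy chain of eye muscle, fell by 0.77 ± 0.12 (1933 ± 211 to 1115 ± 93.5 CPM, adjusted p = 0.00198). Pvalb, the calcium buffer of fast fibres, rose by 0.51. The fast fibre list had 9 higher and 1 lower of 18 (9 and 2 adjusted over the list alone) but was not called (camera adjusted p = 0.0806). Musk, the receptor kinase of the neuromuscular junction, fell by 0.77, while the receptor-clustering gene Rapsn rose by 0.68. The cell cycle inhibitor Cdkn1a rose by 1.21 ± 0.12 (50.1 to 114 CPM, adjusted p = 5.4e-04), and Mstn, the inhibitor of muscle growth, fell by 0.78. The tendon and fibroblast matrix list had 1 higher and 10 lower of 25 (1 and 13 adjusted over the list alone, camera adjusted p = 9.3e-05, adjusted p = 0.807 with an estimated correlation). Col14a1, a collagen of tendon, fell by 1.25, and Postn, a matrix protein of fibroblasts, by 1.02. Igf1, a growth factor for muscle, fell by 1.22 ± 0.09 (129 to 54.9 CPM, adjusted p = 2.9e-04), and Lifr, a cytokine receptor, by 1.00. The endothelial genes Cldn5 and Egfl7 rose by 1.77 and 1.44, but their list had 6 higher and 4 lower of 20 (6 and 5 adjusted over the list alone) and was not called (camera adjusted p = 0.734). The interferon response list had 5 higher and 1 lower of 20 (5 and 1 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.807 with an estimated correlation).

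Some of the largest rises in EOM belonged to genes of other tissues. Gh, the growth hormone of the pituitary, read 0.674 and 9.75 CPM in the albino libraries and 0 in the 4 C57BL/6 libraries. Ttr, a transport protein made by the choroid plexus, read 0.915 and 7.12 CPM against a mean of 0.0338. Snap25 read 7.71 and 56.9 CPM in these libraries, the first within the 5.87 to 34.2 CPM of C57BL/6 EOM. The call of Pomc, a pituitary hormone precursor (log2 fold change 3.50, adjusted p = 0.0202), was lost without albino EOM 3. Without that library 2738 genes were called in EOM. With the level of the Y-linked genes as a covariate 155 were called, and of the EOM genes given here Arntl, Per2, Ciart, Dbp, Hlf, Pdk4, Ucp3, Cdkn1a, Col14a1, Postn, Igf1, Lifr and Egfl7 kept their calls. Y-linked Uty read 16.4 to 19.3 CPM in the libraries labelled albino EOM and 27.8 to 43.1 in C57BL/6 EOM, without overlap. The covariate may therefore stand in for genotype here too, and it does not decide these calls.

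In TA most tested genes of immune cells and of connective tissue were called higher in the matching albino libraries, although neither list was called with an estimated correlation (adjusted p = 0.481 for both). Arntl, Per2 and Dbp shifted in the same sense as in EOM. Transcripts of neurons appeared too, with Snap25 at 2.84 and 0.970 CPM in the albino libraries and at 0 in the 4 C57BL/6 libraries. Of 13295 genes, 4131 (31.1%) were called, 1950 higher and 2181 lower, which became 2442 and 1745 with upper quartile factors and 2721 and 1421 with all tissues in 1 fit, and of the 659 that changed at least 2-fold 527 were higher. Without albino TA 3 2484 genes were called, and with the Y-linked level as a covariate 1239.

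The list of macrophages, microglia and leukocytes had 18 higher and 0 lower of 21 genes in TA (19 adjusted over the list alone, camera adjusted p = 2.4e-14, adjusted p = 0.481 with an estimated correlation). Lyz2, the lysozyme of macrophages, rose by 2.14 ± 0.10, from 19.4 to 86.9 CPM (adjusted p = 7.0e-08). Csf1r, the receptor on which macrophages depend, rose by 1.98, and the antigen presentation genes H2-Aa and Cd74 by 1.89 and 1.81. The tendon and fibroblast matrix list had 23 higher and 0 lower of 25 (23 adjusted over the list alone, camera adjusted p = 1.1e-18, adjusted p = 0.481 with an estimated correlation). Fbn1, the fibrillin of elastic fibres, rose by 1.83 ± 0.11 (14.1 ± 2.13 to 51.3 ± 2.38 CPM, adjusted p = 5.9e-07), and fibronectin (Fn1) by 1.27. Dkk3 rose by 2.85 ± 0.16, from 11.4 ± 2.87 to 84.5 ± 16.9 CPM (adjusted p = 5.9e-07, chromosome 7, 112116017 to 112159057). Cldn5 and Kdr, genes of the vessel wall, rose by 2.06 and 0.82, but the endothelial list was not called (7 higher and 2 lower of 20, 8 and 2 adjusted over the list alone, camera adjusted p = 0.0548). Rn45s, the ribosomal precursor transcript, took 0.843% and 1.77% of the albino TA counts and 0.203% to 0.483% of the C57BL/6 TA counts.

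Arntl rose in TA by 2.30 ± 0.11, from 7.87 ± 0.772 to 39.6 ± 3.43 CPM (adjusted p = 7.5e-08), and Per2 fell by 2.35 and Dbp by 1.45. The clock list had 3 higher and 12 lower of 19 in TA (3 and 12 adjusted over the list alone, camera adjusted p = 3.4e-04, adjusted p = 0.613 with an estimated correlation). Fbxo32, a ubiquitin ligase of muscle atrophy, rose by 1.13 ± 0.15 (375 ± 87.5 to 839 ± 56.1 CPM, adjusted p = 1.9e-04), while Hk2, the hexokinase of muscle, fell by 0.56 and Actn3, the actinin of fast fibres, by 0.50. Fatty acid oxidation had 9 higher and 0 lower of 20 (12 adjusted over the list alone, camera adjusted p = 1.9e-04), with Fabp3 up by 0.79 and Eci1 by 0.55. The respiratory list had 20 higher and 0 lower of 44 (21 adjusted over the list alone, camera adjusted p = 2.4e-06) and the ribosomal list 17 higher and 2 lower of 38 (20 and 3 adjusted over the list alone, camera adjusted p = 0.000999). These 3 lists had an adjusted p = 0.820 with an estimated correlation. With GC and length offsets the respiratory and ribosomal lists lost their calls (camera adjusted p = 0.180 and 0.465).

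**Figure D2:**
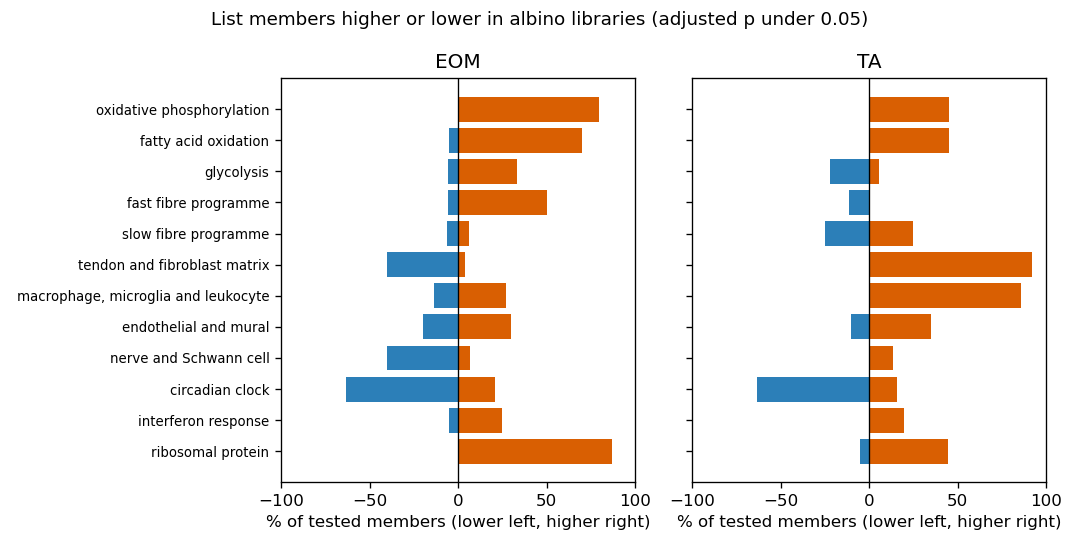
Percentage of the tested members of 12 gene lists called higher (bars to the right) and lower (bars to the left) in albino than in C57BL/6 matching libraries of EOM and TA. The matrix list has 1 higher and 10 lower of 25 genes in EOM and 23 higher and 0 lower in TA.

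**Figure D3:**
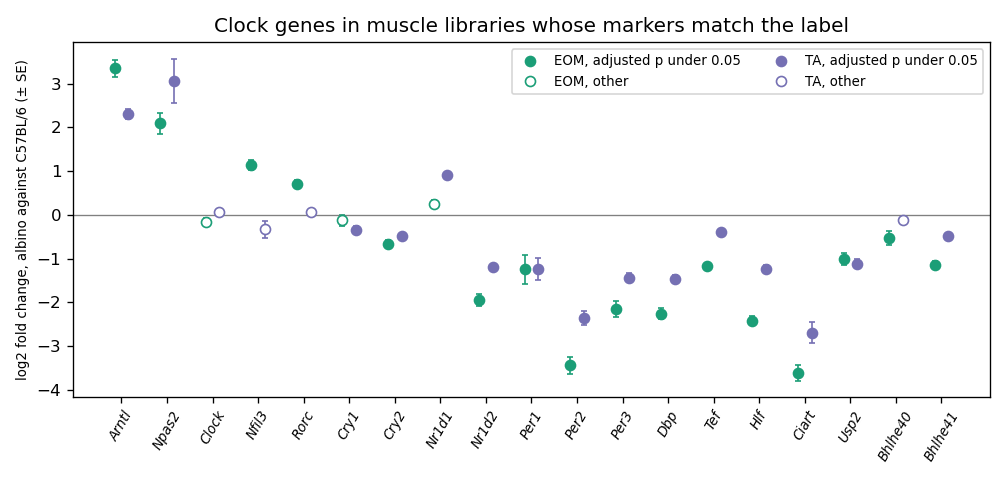
Log2 fold change (albino against C57BL/6, matching libraries, with the standard error) of the 19 clock genes in EOM and TA, with filled points for genes called at an adjusted p under 0.05. Arntl lies at 3.35 in EOM and 2.30 in TA, and Per2 at −3.44 and −2.35.

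The genotype difference itself differed between the muscles for 1211 of 15670 genes, 350 with a higher value in EOM and 861 with a lower one. DESeq2 called 1924 genes here and edgeR with the replicate block 2279. The difference was lower in EOM for 23 of 25 matrix genes and 17 of 22 leukocyte genes and higher for 0, although lists were not tested on this difference. Ddr2, a collagen receptor, fell by 0.89 in EOM and rose by 0.87 in TA, a difference of −1.76 ± 0.12 (adjusted p = 8.4e-06). Ogn, a small matrix proteoglycan, fell by 1.24 and rose by 0.74. In the other direction Rab27a, which carries pigment and secretory granules, rose by 0.80 in EOM and fell by 1.39 in TA, a difference of 2.19 ± 0.23 (adjusted p = 8.1e-05). Nnt fell in both muscles and less in EOM, by a difference of 1.03 ± 0.13 (adjusted p = 3.9e-04). Of the clock genes 3 differed upward and 8 downward of 19, and 6 and 0 of 44 respiratory genes. The count was 591 without albino EOM 3, 605 without albino TA 3 and 593 without albino TA 4.

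In CN3 the matching albino libraries carried transcripts of cholinergic and serotonergic neurons that the C57BL/6 CN3 libraries almost lacked. Few other genes were called. C57BL/6 CN3 held 0.433 CPM of Chat and 0.110 CPM of Slc18a3, against 15.7 and 12.1 CPM in C57BL/6 CN6. Both belong to the cholinergic list of motor neuron genes, so the low values in C57BL/6 CN3 go with samples that held few such neurons. The values therefore do not separate a change in albino mice from a difference in what the samples of either genotype hold. The same applies to CN6. Of 16171 genes 13 were called, 11 higher and 2 lower, and 1344 had an unadjusted p under 0.05. Another split of the same libraries called 28 genes, so chance is not excluded for this count. Chat, the enzyme that makes acetylcholine (chromosome 14, 32408203 to 32465989), rose by 4.89 ± 0.40, from 0.433 ± 0.213 to 12.6 ± 5.81 CPM (adjusted p = 0.00898). Slc18a3, the vesicular acetylcholine transporter, lies within the span of Chat and rose by 6.11 (adjusted p = 0.0160), and the choline transporter Slc5a7 rose by 4.18 (adjusted p = 0.0175). Tph2, the enzyme that makes serotonin in neurons (chromosome 10, 115078641 to 115185022), rose by 6.69 ± 0.52, from 1.57 ± 1.11 to 162 CPM (adjusted p = 0.00774). Its 2 albino values were 90.6 and 233 CPM. The serotonin transporter Slc6a4 rose by 6.82 (adjusted p = 0.0316), Slc17a8, a glutamate transporter, by 3.99, and En1, a factor of midbrain and anterior hindbrain identity, by 2.95. For comparison, C57BL/6 CN6 held 15.7 ± 4.77 CPM of Chat and 9.70 ± 5.13 CPM of Tph2.

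The cholinergic list had 4 higher and 0 lower of 21 genes in CN3 (15 adjusted over the list alone, camera adjusted p = 4.7e-20), the serotonergic and noradrenergic list 2 of 12 (8 adjusted over the list alone, camera adjusted p = 5.7e-08) and the midbrain list 1 of 17 (4 adjusted over the list alone, camera adjusted p = 5.3e-07). With an estimated correlation the adjusted p was 0.206 for each of these 3. The clock list was lower (0 of 19 genes called, 0 adjusted over the list alone, camera adjusted p = 0.00796, adjusted p = 0.820 with an estimated correlation). The choroid plexus list was higher (0 of 16 called, 1 adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.820 with an estimated correlation). The gene count was 7 without C57BL/6 CN3 1 or 3, 4 without C57BL/6 CN3 4, 2 without albino CN3 2, 0 with the Y-linked level as a covariate and 101 by DESeq2. Without albino CN3 2 Chat, Slc18a3, Slc5a7, Slc6a4, Slc17a8 and En1 lost their calls and Tph2 kept its own (adjusted p = 0.0438). Without C57BL/6 CN3 4 Tph2 and all of these but En1 lost theirs. Slc6a4, Slc5a7 and Slc17a8 lost theirs without C57BL/6 CN3 1, Slc18a3 and Slc17a8 without C57BL/6 CN3 3, Slc17a8 without C57BL/6 CN3 2, and Slc6a4 and En1 without albino CN3 1.

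In CN6 4 of 16268 genes were called, 1 higher and 3 lower, and 3 of these were the genes that changed in every tissue. The other was Gabra2, a subunit of the GABA receptor, which fell by 1.22 ± 0.10 (54.5 ± 4.73 to 23.5 ± 2.22 CPM, adjusted p = 0.00153). Whether its fall reflects the C57BL/6 substrain or albinism was not tested. Camera called 10 lists in CN6 at the preset correlation and 0 with an estimated one, and fry called 0. Of 15 splits 7 called as many lists, the real one included. The lists given here had 0 called members. The hindbrain Hox list was lower (0 of 12 called, 6 adjusted over the list alone, median log2 fold change −1.66, camera adjusted p = 2.1e-10, adjusted p = 0.510 with an estimated correlation). The serotonergic and noradrenergic list was higher (0 of 12 called, 10 adjusted over the list alone, camera adjusted p = 8.7e-09, adjusted p = 0.510 with an estimated correlation). So were the midbrain list (0 of 15 called, 9 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.566 with an estimated correlation) and the ribosomal list (0 of 38 called, 0 adjusted over the list alone, camera adjusted p = 2.1e-10, adjusted p = 0.510 with an estimated correlation). The oligodendrocyte list was lower (0 of 20 called, 0 adjusted over the list alone, camera adjusted p = 8.0e-06, adjusted p = 0.591 with an estimated correlation). The 2 albino libraries differed from each other, and albino CN6 1 lay far from C57BL/6 CN6 in both genes that follow. Its site therefore stays open. The Hox, serotonergic and midbrain lists may rest on that library, which was not tested. Hoxb3 read 2.61 and 20.8 CPM in albino CN6 1 and 2, against 23.0 to 31.4 CPM in C57BL/6 CN6, and Tph2 244 and 11.5 CPM against 5.30 to 17.1. The count was 950 without albino CN6 2, 9 without albino CN6 1 and 106 by DESeq2. With the replicate block edgeR called 0, with 627 at an unadjusted p under 0.05.

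**Figure D4:**
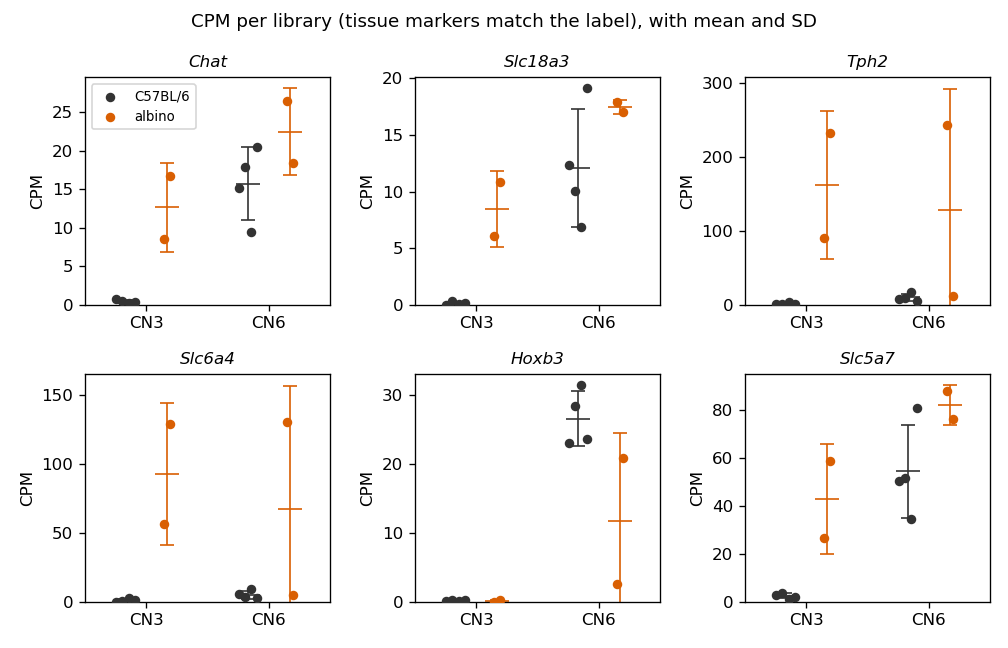
Expression (CPM) of Chat, Slc18a3, Tph2, Slc6a4, Hoxb3 and Slc5a7 in the CN3 and CN6 libraries whose markers match their label, with a point per library and the mean and SD of each group. Albino CN3 holds 90.6 and 233 CPM of Tph2 and C57BL/6 CN3 at most 3.23 CPM.

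The genotype difference differed between CN3 and CN6 for 2 of 16604 genes, Chat by 4.39 ± 0.54 and Slc18a3 by 5.57 ± 0.72 (adjusted p = 0.0286 for both). In CN6 neither was called (log2 fold change 0.50 and 0.52). The count was 0 without C57BL/6 CN6 1, C57BL/6 CN6 2, C57BL/6 CN3 3, C57BL/6 CN3 4, albino CN6 1 or albino CN3 2. It was 6 without C57BL/6 CN3 2, 4 without albino CN3 1, 20 without albino CN6 2, and 0 by limma voom or with the Y-linked covariate.

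Genes called in every tissue were few and lie on different chromosomes. Of 12768 genes tested in all 4 tissues, Nnt and Wdfy1 were lower and Ide higher in each. These calls did not hold in the nuclei under every setting. In CN3 Nnt lost its call without C57BL/6 CN3 1, 3 or 4 or either albino library, and Ide without C57BL/6 CN3 4 or either albino library. With the Y-linked covariate all 3 lost theirs in CN3 and with the replicate block in CN6. Under either no gene was called in every tissue, but neither setting can decide these calls. Y-linked Ddx3y read 94.8 ± 6.74 CPM in albino and 50.4 ± 11.6 in C57BL/6 CN3, without overlap, so the covariate overlaps with genotype. Kdm5d, Uty and Eif2s3y differed less there. Every library held Ddx3y and at most 0.258 CPM of Xist, so no difference in sex was seen. The block leaves little spread to test against among 6 libraries. In CN6 equal replicate numbers of the genotypes had residual correlations of only −0.13 and 0.016. Nnt (chromosome 13, 119335448 to 119408997), the transhydrogenase that supplies NADPH to mitochondria, fell by 1.53 in EOM, 2.57 in TA, 1.01 in CN3 and 1.09 in CN6. Over the 4 tissues together it fell by 1.53 ± 0.05 (adjusted p = 1.7e-14). Wdfy1, an endosomal adaptor (chromosome 1, 79702262 to 79776143), fell by 1.97 ± 0.06 over the tissues (adjusted p = 1.8e-15), from 39.9 ± 3.73 to 8.63 ± 0.0185 CPM in EOM. Ide, the insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), rose by 0.75 ± 0.04 (adjusted p = 9.7e-12). Entpd4, a nucleotidase of the Golgi apparatus (chromosome 14, 69337174 to 69367270), rose by 0.98 ± 0.05 (adjusted p = 1.0e-10), although its near-identical copy Entpd4b makes the assignment of reads uncertain. In CN3 and CN6 it missed the threshold (adjusted p = 0.0631 and 0.0532). All 4 are among the 12 substrain markers, of which 9 had counts in each tissue and 7 were called, with Fgfbp3 at 0.61, Dock2 at 0.50 and Cyfip2 at 0.22 (adjusted p = 0.0497).

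**Figure D5:**
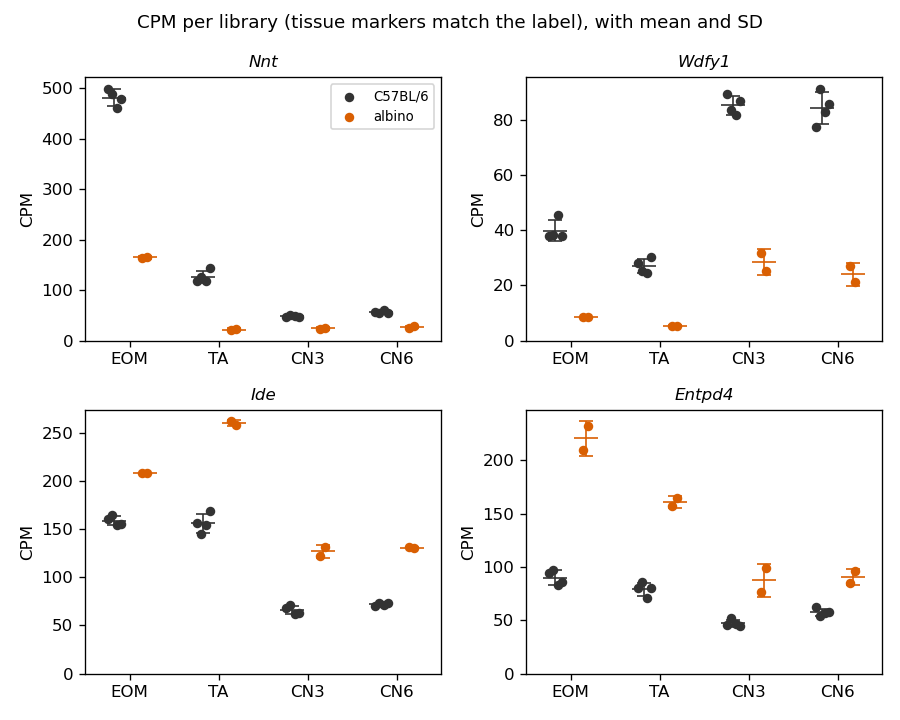
Expression (CPM) of Nnt, Wdfy1, Ide and Entpd4 in the matching libraries of the 4 tissues by genotype, with a point per library and the mean and SD. In TA Nnt averages 21.7 CPM in albino and 126 CPM in C57BL/6 libraries.

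Called genes were shared mainly between the muscles. Of the genes tested in both, 852 were higher in both EOM and TA where chance gives 322 (adjusted p = 3.3e-217, one-sided Fisher exact test), and 1352 were lower in both where chance gives 434 (log10 p = −519). Only 23 and 129 were called in opposite directions. The Fisher test takes genes as independent, and the overlap was not repeated with GC and length offsets. Fold changes followed GC content in both EOM and TA (Spearman correlation 0.50 and 0.42) and length too (−0.42 and −0.22). A bias shared by the muscles is therefore not excluded as a source of the overlap. Altogether 2204 genes were called in the same direction in at least 2 tissues and 4 in at least 3, the fourth being Asb4, a ubiquitin ligase adaptor, which rose by 1.02 in EOM, 0.51 in TA and 1.81 in CN3. CN3 and CN6 shared 2 lower genes and 1 higher gene (adjusted p = 9.5e-08 and 0.00207), and no other pair shared more than chance at an adjusted p under 0.05 (lowest 0.0556). Fitted over the 4 tissues together, 4385 of 17432 genes were called, 2372 higher and 2013 lower, and 2789 with GC and length offsets. The replicate block lowered the 2204 shared genes to 1446. Called genes were not more frequent near Tyr, with 22 of 100 tested genes within 10 Mb called in EOM and 19 of 91 in TA.

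EOM and TA differed from each other in most genes, 12127 of 15670 (77.4%), with 6639 higher in EOM. Eye muscle was set apart by its own myosins. Myh15 was higher by 11.82 ± 0.19 (adjusted p = 3.9e-15) and Myh13, the superfast myosin of eye muscle, by 6.65 ± 0.12. The embryonic myosin Myh3 was higher by 7.53 and Sln, a regulator of the calcium pump, by 6.17. The EOM-type myosin list had 11 higher and 0 lower of 12 genes and the fast fibre list 1 higher and 17 lower of 18. TA held the Hox genes of the limb, with Hoxa9, Hoxa10 and Hoxc10 lower in EOM at −11.30, −11.13 and −10.10, and Myom2, of the fast fibre M-band, at −8.24. EOM also carried epithelial and gland genes. Krt13, a keratin of moist epithelia, was higher by 11.20, and of 16 lacrimal and Harderian gland genes 14 were higher and 0 lower. The sample may therefore hold tissue next to the muscle fibres, which was not tested. The leukocyte list had 22 of 22 genes higher in EOM, the nerve list 15 of 15 and the neuromuscular junction list 12 of 15, while respiratory genes had 1 higher and 40 lower of 44.

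CN3 and CN6 differed in 3201 of 16604 genes, 1547 higher in CN3 and 1654 lower, and 470 of them changed at least 2-fold. The hindbrain genes followed the position of the nuclei. All 12 tested Hox genes were lower in CN3, led by Hoxb3 at −7.18 ± 0.64 (adjusted p = 6.1e-05). Otx2, a factor of forebrain and midbrain, was higher by 3.70 ± 0.49 (adjusted p = 5.9e-04). The dopamine transporter Slc6a3 was higher by 5.54. Averaged over the genotypes, Chat and Slc18a3 were lower in CN3, at −3.03 and −3.84, values that describe neither genotype. Chat read 0.433 against 15.7 CPM in C57BL/6 CN3 and CN6 and 12.6 against 22.5 CPM in the albino ones, and Slc18a3 0.110 against 12.1 and 8.45 against 17.5 CPM. The cholinergic list had 0 higher and 19 lower of 23 genes. The noradrenergic genes Dbh and Slc6a2 were lower too, at −3.97 and −4.29. Of the midbrain list 8 of 17 were higher, and of the respiratory list 24 of 44 were lower. The count was 1212 without albino CN3 1 and 1133 without albino CN6 2.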

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

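Chosen after the results were seen were the tests on the contradicted labels, those on Nnt, Wdfy1, Ide and Entpd4, and that on the time of day. The tests on GC content, on length and on all calls near Tyr were set out before their results, and the set of libraries whose markers match their label was chosen after seeing the data.

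The contradicted labels come first, since every comparison rests on them. In 8 albino libraries the genes of the labelled kind of tissue were almost absent. A mixture with the other tissue is argued against, because Ckm or Snap25 reached at most 0.512% of the lowest matching albino library of the group. An effect of the albino genotype is argued against too, since 2 of the 4 albino libraries in each group matched their label. Column names given in another order may be the source. Equal numbers are out of place in muscle and in brain, and the kind of tissue changes 1 time along the 16 albino columns. The exact p = 0.000155 over random orders restates the pattern that prompted the test, so it is no separate evidence. Within the albino libraries that look like brain, Hoxb3 read 0 and 0.0579 CPM in those labelled EOM. It read 21.3 and 11.6 CPM in those labelled TA. Of those that look like muscle, the 2 labelled CN3 held 5320 and 5462 CPM of Ckm, and matching albino EOM 5569 and 5806. The 2 labelled CN6 held 13007 and 13325 CPM, and matching albino TA 14488 and 14902. These values go with an exchange of EOM with CN3 and of TA with CN6 in these 8 libraries. Which column belongs to which sample stays open, as no library was moved.

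Nnt, Wdfy1, Ide and Entpd4 changed across the tissues together. A chromosome segment inherited around Tyr is argued against, since 0 of these 4 genes lie on chromosome 7. For all genes called over the 4 tissues the odds ratio of chromosome 7 was 0.904 (one-sided Fisher exact p = 0.937). Nnt, Wdfy1 and Ide, the only 3 genes called in all 4 tissues of 12768 tested there, are among the 12 substrain markers fixed beforehand. That goes with different C57BL/6 substrains behind the genotypes. An effect of albinism on these genes cannot be told apart from it, since genotype and substrain would be confounded. Of the 5 other substrain markers with counts in each tissue 3 were called, against 27.1% of other such genes. With an odds ratio of 4.04 (one-sided Fisher exact p = 0.127) these are too few markers to decide. That test leaves out Nnt, Wdfy1, Ide and Entpd4 and ignores direction. Crb1, a marker without counts in each tissue, was higher by 2.05 in CN3 and 2.45 in CN6. It was not called by edgeR (adjusted p = 0.0771 and 0.110). The labels do not name the C57BL/6 substrain, and the effect of albinism on these genes was not tested. The same limit applies to every genotype difference given here.

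The calls in muscle make up the third pattern, in which 35 of 44 respiratory genes were called higher in EOM and 20 of 44 in TA, and clock genes shifted in both. With GC and length offsets the count of called genes in EOM went from 4934 to 1733, of which 1368 were among the 4934, so a bias of GC content and length may account for much of it. In TA 3676 were called, of which 2625 were among the 4131. Such a bias could explain the respiratory list in TA, whose median log2 fold change went from 0.15 to 0.00085 and whose camera adjusted p became 0.180, but not the whole of that in EOM, which stayed called at 9.9e-07 with its median going from 0.45 to 0.18. That call uses the preset correlation, and before the correction the list had an adjusted p = 0.807 with an estimated one, and only 8 of its 35 called genes stayed called. Bias of that kind is argued against for the clock genes, of which 15 of 16 called stayed called in EOM and 15 of 15 in TA. Collection of the genotypes at different times of day, which the labels do not give, and an effect of albinism on the clock cannot be told apart, since genotype and time would be confounded, and Arntl moved against Per2, Dbp and Hlf by at least 3.76 on the log2 scale in both muscles.

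Single libraries stood far from the other 3 of their group in 6 of 44 groups tested, and chance alone marks about 1 in 20 groups. Rn45s, a ribosomal precursor whose share depends on how RNA was prepared, took 1.31% of C57BL/6 EOM 3 against 0.130% to 0.264% in the others of that group. It took 0.0424% of C57BL/6 CN3 4 against 0.0145% to 0.0175%, and 10.6% of the library labelled albino CN6 4 against 0.0245% to 1.13%. The summed Y-linked genes read 140.5 CPM in C57BL/6 CN6 1 against 146.7 to 147.1 CPM. Wdfy1 read 45.5 CPM in C57BL/6 EOM 3 against 38.0 to 38.2 CPM, and Tph2 3.23 CPM in C57BL/6 CN3 3 against 0.859 to 1.11 CPM.

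A difference of the genotype effect between tissues stood out where its own test called genes. As labelled, 33 genes differed between EOM and TA. In the matching libraries 1211 differed between EOM and TA and 2 between CN3 and CN6. Without albino EOM 3, albino TA 3 or albino TA 4 the 1211 became 591, 605 and 593. The 2 became 0 without C57BL/6 CN6 1, C57BL/6 CN6 2, C57BL/6 CN3 3, C57BL/6 CN3 4, albino CN6 1 or albino CN3 2, and 6, 4 and 20 without C57BL/6 CN3 2, albino CN3 1 and albino CN6 2. The 33 ran from 0 to 160, as given for each library in the report.

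Tested one by one, the genes named for these differences bring their own sizes. Rab27a differed between EOM and TA by 2.19, Asb11 by 1.05, Nnt by 1.03, Hoxc10 by 4.53 and Pdcd5 by 0.72, and in the other direction Ddr2 by −1.76, Ogn by −1.98, F13a1 by −2.23 and C3 by −1.57. Hoxc10 had too few counts in EOM for a genotype test there, so its value rests on trace counts, and in TA it was not called (log2 fold change −0.04, adjusted p = 0.745). Between CN3 and CN6 Chat differed by 4.39 and Slc18a3 by 5.57.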

How the results depend on the processing

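With all libraries as labelled, the counts moved widely with the processing, and the cause was not tested. In EOM, where 1 gene was called, upper quartile factors called 4, the stricter filter 39, DESeq2 3796, limma voom 12754, all tissues in 1 fit 827, the Y-linked covariate 0 and the replicate block 0. In TA, where 18 were called, DESeq2 size factors called 1, upper quartile factors 10, no filter 1, the stricter filter 74, DESeq2 3371, limma voom 11121, all tissues in 1 fit 5375, the Y-linked covariate 1 and the replicate block 0. From 0 called genes, DESeq2 called 1235 in CN3 and 777 in CN6, limma voom 16 and 2, and all tissues in 1 fit 3 and 1. The 33 genes whose genotype difference differed between EOM and TA became 12 with no filter, 881 by DESeq2, 8968 by limma voom, 245 with all tissues in 1 fit, 0 with the Y-linked covariate and 700 with the replicate block. Between CN3 and CN6 0 became 12 by DESeq2. The 4345 genes that differ between EOM and TA became 9077 by limma voom, 1934 with the Y-linked covariate and 10728 with the replicate block. The 28 between CN3 and CN6 became 446 by DESeq2, 2501 by limma voom, 103 with all tissues in 1 fit and 728 with the replicate block. Genes shared between tissues went from 0 to 105 at an adjusted p under 0.10, to 2198 by DESeq2 and to 3 with the stricter filter. Lists called went to 0 in each of the 4 tissues with an estimated correlation, and to 4, 4, 0 and 0 in EOM, TA, CN3 and CN6 with fry. Only the matching libraries gave 4934, 4131, 13 and 4 genes in EOM, TA, CN3 and CN6, 1211 and 2 for the genotype by tissue tests, 12127 and 3201 for the tissues, 7 lists in EOM and 5 in CN3 and 2204 shared genes. Leaving out 1 library gave 0 to 2206 genes in EOM, 0 to 2578 in TA, 0 to 0 in CN3 and 0 to 1 in CN6. It gave 0 to 160 and 0 to 0 for the genotype by tissue tests of the muscles and the nuclei, 3421 to 5061 and 16 to 76 for the tissues, and 9 to 20, 2 to 11, 11 to 16 and 11 to 16 lists in EOM, TA, CN3 and CN6. The libraries behind these ranges are named in the report.

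In the matching libraries the counts of EOM and TA stayed within 1.5 times of 4934 and 4131 under both other scalings, both filters, DESeq2, limma voom and all tissues in 1 fit, and the cause was not tested where they did not. EOM went to 155 with the Y-linked covariate, 2641 with the replicate block and 1733 with GC and length offsets, and TA to 1239 with the Y-linked covariate. From 13 genes, CN3 went to 21 with no filter, 101 by DESeq2, 20 by limma voom, 49 with all tissues in 1 fit, 0 with the Y-linked covariate and 5 with the replicate block. From 4 genes, CN6 went to 21 with no filter, 106 by DESeq2, 8 by limma voom, 12 with all tissues in 1 fit, 7 with the Y-linked covariate and 0 with the replicate block. The covariate overlaps with genotype in CN3 and, through Uty, in EOM, and the block leaves little spread to test against in CN6. The 0 with the covariate in CN3, the 155 with it in EOM and the 0 with the block in CN6 therefore do not decide the calls there. The 1211 genes of the genotype by tissue test in muscle became 1924 by DESeq2 and 2279 with the replicate block. The 2 genes of that test in the nuclei became 11 by DESeq2, 0 by limma voom, 4 with all tissues in 1 fit, 0 with the Y-linked covariate, 3 with GC and length offsets and 4 with the replicate block. Over the 4 tissues 4385 became 2789 with GC and length offsets. Shared genes went from 2204 to 1054 at an adjusted p under 0.01 and 1446 with the replicate block. Lists called went to 0 in each tissue with an estimated correlation and to 0 in CN3 and 0 in CN6 with fry. Upper quartile factors moved the balance of directions in EOM to 2881 higher and 2390 lower and in TA to 2442 and 1745, and all tissues in 1 fit to 3174 and 2773 and to 2721 and 1421. Leaving out 1 library gave 2738 to 4811 genes in EOM, 2484 to 3849 in TA, 2 to 12 in CN3 and 4 to 950 in CN6. It gave 591 to 1351 and 0 to 20 for the genotype by tissue tests, 11561 to 12054 and 1133 to 3615 for the tissues, 3446 to 4618 over the 4 tissues, and 6 to 10, 5 to 9, 4 to 8 and 8 to 13 lists, with 8 in CN3 without albino CN3 2. Where 1 albino library is left, it is assumed to vary like the others.

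Of the named genes, 120 in EOM gave 1188 values over 10 settings, of which 973 kept direction and side of the threshold, 207 lost the call, 2 gained it and 6 changed direction. In TA 112 genes gave 1110 values, with 1013 kept, 92 lost, 1 gained and 4 changed in direction. In CN3 190 of 226 and in CN6 124 of 139 were kept and 0 changed direction. With the Y-linked covariate Gh in EOM became −1.80 and Cfd in TA −0.0384. With GC and length offsets Kdm5d in EOM became 0.0793, Tnnc2 −0.0414, Pgam2 −0.14, Pnpla2 −0.0833 and Rps15 −0.0347, and in TA Pnpla2 became −0.000267, Hspb1 −0.0201 and Atf4 −0.000384. The cause of these was not tested. The replicate numbers showed no pairing of the C57BL/6 samples, where residual correlations of EOM and TA with the same number ran from −0.003 to 0.085 and those of CN3 and CN6 from −0.16 to 0.13. In albino libraries as labelled they ran from 0.81 to 0.87 and from 0.84 to 0.88, where equal numbers share the contradicted kind of tissue. In the matching albino libraries they were 0.177 and 0.189, each a single value since 2 residuals mirror each other, so pairing there stays open. Depth limits genes such as Tyr, which stays below 1 CPM. On simulated data of this size 28.4% of genes changed 1.5-fold were recovered in EOM, 59.7% in TA, 34.8% in CN3 and 47.0% in CN6.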

Other observations

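Gene lists tied to albinism and nystagmus were not called by camera in the matching libraries. The pigment list had 0 higher and 2 lower of 10 genes in EOM (0 and 2 adjusted over the list alone, camera adjusted p = 0.297). Mitf, the regulator of pigment cells, fell by 0.69 and Tyrp1, a melanin enzyme, by 1.11, and Tyrp1 lost its call without albino EOM 3 or 4. In TA the list had 0 higher and 1 lower of 3 genes (0 and 1 adjusted over the list alone), and in CN3 and CN6 0 of 7 were called. The nystagmus list had 1 higher and 4 lower of 10 in EOM (1 and 4 adjusted over the list alone, camera adjusted p = 0.446). Cacna1a, a calcium channel subunit, rose by 0.63 and lost its call without albino EOM 3, and Lyst, a gene of lysosome trafficking, fell by 0.95. In TA 0 higher and 1 lower of 5 were called, and 0 of 11 in CN3 and in CN6, where the median was 0.09 and 0.05 and the mean −0.005 and −0.03, of opposite sign.

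Signalling lists were mixed. The growth factor list had 1 higher and 6 lower of 26 in EOM (1 and 6 adjusted over the list alone, camera adjusted p = 0.446, fry adjusted p = 0.0171) and 5 higher and 4 lower of 24 in TA. The retinoid list had 5 higher and 1 lower of 17 in EOM (5 and 1 adjusted over the list alone) and 6 higher and 2 lower of 15 in TA (8 and 2 adjusted over the list alone, camera adjusted p = 0.122, fry adjusted p = 0.00821). Aldh1a2, which makes retinoic acid, rose by 2.01 in TA. The hedgehog and Wnt list had 3 higher and 6 lower of 22 in EOM and 4 higher and 2 lower of 20 in TA (fry adjusted p = 0.0172), and was lower in CN6 (0 of 26 called, camera adjusted p = 0.0103, adjusted p = 0.510 with an estimated correlation). The immediate early list had 5 higher and 1 lower of 22 in EOM and 3 higher and 0 lower of 21 in TA, with Junb up by 1.29 and 1.63. In CN6 the immediate early, interferon and glutamatergic lists were higher and the respiratory list lower with 0 called genes each (camera adjusted p = 0.0313, 0.0267, 0.00907 and 4.7e-04, adjusted p = 0.585, 0.537, 0.591 and 0.672 with an estimated correlation). In EOM the neuromuscular junction list had a median of 0.04 and a mean of −0.002, and in TA the EOM-type myosin list a median of 0.02 and a mean of −0.16, so these measures differ in sign, and neither list was called.

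Other splits of the same libraries were tested in place of the real one, and the splits of the matching libraries were run after that set had been chosen from the data. As labelled, 1 of 35 splits in EOM gave as many genes as the real one (1, highest other 0) and 1 of 35 in TA (18, highest other 0), the real one itself, so chance is excluded at that share. That says little for these counts, since the groups mix muscle with brain and the count in EOM became 0 without C57BL/6 EOM 1 or 4 and that in TA 0 without any single C57BL/6 TA library or albino TA 1. In CN3 and CN6 35 of 35 did (0 genes, highest other 0). For lists 9 of 35 splits did in EOM (19, highest other 21), 16 in TA (7, highest other 14), 4 in CN3 (15, highest other 16) and 13 in CN6 (13, highest other 18), so chance is not excluded. The genotype by tissue tests gave 11 of 100 splits in muscle (33, highest other 6065) and 100 of 100 in the nuclei (0, highest other 3026), and the tissue comparisons 4 of 100 in each (4345, highest other 10323, and 28, highest other 11735). Splits that call many times more genes than the real one may point to a structure of the samples, such as muscle and brain under 1 label. Which libraries those splits put together was not examined. Of the genes shared between tissues as labelled, 100 of 100 splits gave as many (0, highest other 0).

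In the matching libraries 15 splits per tissue are too few for a share under 0.05. The real values and the highest others were 4934 and 0 genes in EOM (1 split as large), 4131 and 0 in TA (1), 13 and 28 in CN3 (2) and 4 and 1 in CN6 (1). For lists they were 7 and 17 in EOM (14 splits as large), 6 and 12 in TA (10), 5 and 13 in CN3 (13) and 10 and 11 in CN6 (7). For the genes in CN3 and the lists in each tissue more than 1 split was as large, so chance is not excluded there. Chance was excluded for the tissues, with 1 of 100 splits as large for EOM and TA (12127, highest other 2701) and for CN3 and CN6 (3201, highest other 69). For the genotype over the 4 tissues 1 of 100 splits was as large (4385, highest other 3587). These splits moved the genotypes in each tissue apart, which takes the tissues as coming from separate mice. Since pairing of the albino libraries stays open, chance is excluded there only under that assumption. For the genes shared between tissues 1 of 100 was as large (2204, highest other 0). The other splits of EOM and TA called 0 genes each, so that outcome was fixed beforehand and decides nothing.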
